A study of Homo sapiens with 6 samples.

How the data were processed

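The series holds 6 arrays of Caco-2 cells, 3 with control siRNA and 3 with SDC1 siRNA, grouped and numbered by their titles. The design text calls the replicates independent, but nothing says whether they came from separate cultures, so the p-values measure only the spread between these arrays, which may be technical. Biotin-labelled cRNA was hybridized to Affymetrix arrays, per the labels' protocols. The deposited values were made with RMA, per the submitters' processing notes, and are on a log2 scale by the reading of the values given next. RMA corrects background, normalizes by quantiles and summarizes probes into probe sets. Its version and software are not given in the sources used here.

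The deposited log2 values are centred. The median over the 6 arrays was 0 for 54675 of 54675 probe sets (tolerance 1e-06), and the sources used here give no such step. Centring keeps differences between arrays and removes absolute levels, so no detection call, filter on level or comparison between genes' levels could be made. The log base and a rough brightness were read from the values themselves. Single-precision numbers from 8 to 16, from 4 to 8 and from 2 to 4 are stored in steps that differ by factors of 2, and the centred values keep these steps. They placed 9444 probe sets (17.3%) at 8 to 16, 24721 (45.2%) at 4 to 8 and 20510 (37.5%) below 4, a range that log2 RMA values fill and log10 values could not. A probe set that crosses a bound falls into the lower class, and chance can place some a class too high.

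Probe sets were named from the platform annotation supplied for the series: 41091 had 1 gene symbol, 1801 had several and 11721 had none there, and 62 control probe sets were left out. Probe sets with 1 symbol covered 19775 genes. Of these probe sets, 99.9% had an Entrez identifier in the RefSeq gene table used to update symbols. The plan fixed before the data were examined took the probe set with the highest mean per gene. Centred values cannot rank probe sets by level. All probe sets were therefore first tested singly, which called 0. Each gene's value was then set to the mean over its probe sets in its brightest step class, the rule closest to the plan. That rule was chosen after seeing the table and that result, and gene-level fits under 4 rules were run together, with 5, 3, 5 and 1 genes called by the brightest class, the mean of all probe sets, the brightest class without _x_at and _s_at probe sets, and the highest mean of centred values. The planned filter on dim genes was replaced for the same reason by a step class of 4 or higher, and the planned intensity trend was not run. The design for SDC1 named each of its probe sets, and both levels are given.

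Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) over all 6 arrays with the group as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. A positive difference means higher with SDC1 siRNA. Errors on differences are moderated standard errors and intervals are 95% intervals of the fit. The 33 gene lists held 999 genes, of which 916 were measured here. They were tested with camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry as alternatives. Camera compares moderated t statistics, not log2 differences, so its direction can differ from a list's mean or median difference. The proteoglycan list, for example, had a mean of -0.01 and a median of 0.03. The median difference over all genes was 0.01.

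The rule for named genes took SDC1, up to 12 genes past the threshold with separate groups in each direction, then up to 5 with the lowest p where fewer passed, and up to 2 members with the lowest p per list. Alternatives were a replicate block, each array left out, quantile normalization again, arrays centred on their medians, array weights, a robust fit, other rules for probe sets, a stricter adjusted p of 0.01 and a fold of 1.5. The quantile normalization was run on the centred values. It gave the arrays the same distribution of deviations and did not repeat the normalization within RMA. On simulated arrays with the spread of this comparison and 19775 genes, the fit called 80% of 50 genes changed by 0.5 (log2). It called 100% of 50 genes at each of 1, 1.5 and 2, and 15 unchanged genes as well. Camera called a list of 19 genes shifted by 0.2. The simulation assumed independent genes. Its many planted changes loosen the Benjamini-Hochberg cutoff, so the 80% need not hold for data with 5 genes called.

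No 2 arrays held the same values: at most 52 of 19775 gene values were exactly equal, with no tolerance, between any pair. No scan date or other batch is given in the sources used here, so a batch could not be tested.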

Results

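Gene expression was measured on 6 oligonucleotide arrays of total RNA from Caco-2 cells, a human colorectal adenocarcinoma line that forms an enterocyte-like epithelium in culture. Cells had been transfected with a small interfering RNA (siRNA) against SDC1 (3 arrays) or with a negative control siRNA (3 arrays). SDC1 encodes syndecan-1, a transmembrane proteoglycan of epithelial cells that carries heparan sulfate chains. The comparison asks which transcripts depend on SDC1 in these cells. The values were log2 signals relative to each probe set's median over the 6 arrays, so differences between the groups could be read but absolute levels could not. After averaging into 19775 genes, the median absolute difference between 2 arrays ran from 0.09 for SDC1 siRNA replicates 1 and 2 to 0.15 for control replicate 2 and SDC1 siRNA replicate 2. The number of arrays limits the precision of every value below.

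SDC1 was lower in every SDC1 siRNA array than in every control array. Its mean relative log2 signal was 0.36 ± 0.02 (SD, n = 3) with control siRNA and -0.49 ± 0.14 (SD, n = 3) with SDC1 siRNA. The difference was -0.84 ± 0.08 (standard error) on the log2 scale, a 1.79-fold reduction, with a 95% interval from -1.04 to -0.65 and a limma adjusted p = 0.0238 over all genes. The 2 SDC1 probe sets gave -0.83 and -0.85. Tested as single probe sets among all 54613, each had a limma adjusted p = 0.121. Without _x_at and _s_at probe sets, 1 of them stood for the gene and passed among 17098 genes (limma adjusted p = 0.0332). The gene's call was lost after quantile normalization of the centred values (adjusted p = 0.083) and with the highest mean of centred values (adjusted p = 0.0994). The mean of the 2 was -0.50, -0.62 and -0.34 in SDC1 siRNA replicates 1, 2 and 3. An exact two-sided permutation test of 3 arrays against 3 gave p = 0.1 for each probe set, the smallest value this design allows. The limma adjusted p lay between 0.0615 and 0.326 when any 1 of the 6 arrays was left out, past the threshold in none of the 6 fits, and the log2 difference lay between -0.92 and -0.78.

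Besides SDC1, 4 genes changed with SDC1 siRNA. LGSN, which encodes lengsin, a lens protein related to glutamine synthetase, rose by 1.05 ± 0.08 (log2, standard error; 2.07-fold, adjusted p = 0.0127). GPRC5A, an orphan receptor induced by retinoic acid, rose by 0.79 ± 0.07 (1.73-fold, adjusted p = 0.022). ADAMTS18, a secreted metalloproteinase, fell by 1.01 ± 0.10 on the log2 scale (adjusted p = 0.0238), and MPDZ, a scaffold protein of tight junctions with many PDZ domains, fell by 0.72 ± 0.07 (adjusted p = 0.022). In all 5 genes the 3 arrays of one group lay above the 3 of the other. The tests were limma fits with Benjamini-Hochberg adjustment over 19775 genes, and 5 genes passed an adjusted p of 0.05, 2 of them higher and 3 lower. This count depends on how probe sets were combined into genes, by a rule chosen after the values were seen and after a fit of single probe sets had called 0. It was 3 with the mean of all probe sets of a gene (LGSN, MPDZ and SDC1). It stayed at 5, the same genes, without _x_at and _s_at probe sets. Both rules were alternatives set in advance. The count was 1 (LGSN) with the highest mean of centred values, the main rule of the plan applied to values that hold no levels. It was 39 with array weights and 11 among genes of the brighter classes, the 5 genes included in both. Leaving out control replicate 3 kept LGSN alone, and leaving out any other array left 0 genes past the threshold.

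**Figure D1:**
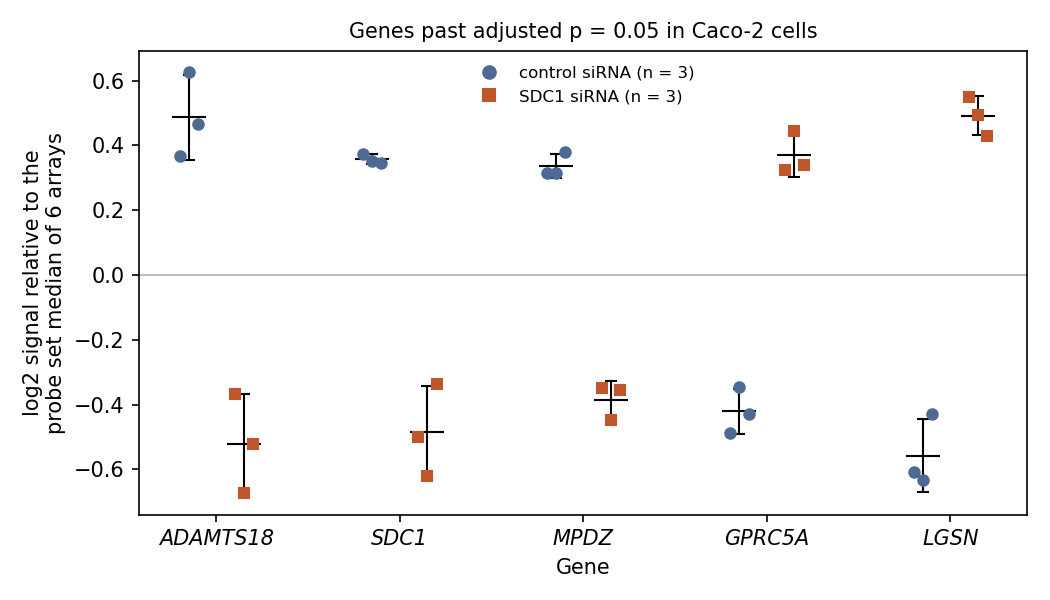
Relative log2 signal of the 5 genes past an adjusted p of 0.05, for each of the 3 control siRNA arrays (circles) and 3 SDC1 siRNA arrays (squares), with the mean (horizontal bar) and SD (error bar). The groups are separate in each gene, and the differences run from -1.01 for ADAMTS18 to 1.05 for LGSN.

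The probe sets behind these genes did not all move. GPRC5A was measured by 2 brighter probe sets with differences of 0.89 and 0.69 and by a dim one with 0.05. ADAMTS18 was measured by a brighter probe set with a difference of -1.01 and a dim one with -0.09. Averaging all probe sets of a gene gave 0.55 for GPRC5A and -0.55 for ADAMTS18, both with an adjusted p = 0.094. The highest mean of centred values picked the dim probe set of each, which left GPRC5A at 0.05 (adjusted p = 0.94) and ADAMTS18 at -0.09 (adjusted p = 0.855). The 2 MPDZ probe sets gave -0.67 and -0.77, and LGSN had 1 probe set. When every probe set was tested singly, the lowest adjusted p was 0.0502 (limma), and 0 of 54613 probe sets passed 0.05, with 4547 at an unadjusted p under 0.05.

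The genes next in order did not pass the threshold. All 10 named here passed with array weights, which were estimated from these same arrays (0.47 for control replicate 2, 1.80 for control replicate 1). The 5 lower ones passed among genes of the brighter classes. In each other setting of the gene fit 0 of the 10 passed, including the fit without control replicate 2. On the lower side were SNAI2, the Slug repressor of epithelial genes, at -0.89 ± 0.11 (adjusted p = 0.067), ODAM at -0.82 ± 0.10, the complement component C5 at -0.69 ± 0.08, the iron reductase CYBRD1 at -0.69 ± 0.08 and SOSTDC1, a secreted antagonist of BMP and Wnt signalling, at -0.63 ± 0.08. On the higher side was FN1, which encodes fibronectin, at 0.61 ± 0.09 (adjusted p = 0.096). Without probe sets of shared sequence types FN1 was at -0.04, measured by dim probe sets alone. Also higher were the transcription cofactor LBH at 0.61 ± 0.09 and the skeletal actin ACTA1 at 0.53 ± 0.08. The FGF carrier FGFBP1 was at 0.53 ± 0.08 and the epithelial membrane protein EMP2 at 0.51 ± 0.07. Each of these 10 genes separated the groups completely, as did 3308 genes in all (16.7%, where chance gives 10%). Across all genes, 2100 reached an unadjusted p under 0.05, against 989 expected by chance. Of these, 1074 were higher and 1026 lower with SDC1 siRNA. At least 1.5-fold differences were seen in 30 genes, and the median absolute log2 difference was 0.08.

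Of 33 gene lists fixed in advance, 0 passed an adjusted p of 0.05 in limma's camera test, which compares a list with all other genes. The lowest adjusted p was 0.189, and 5 lists were at an unadjusted p under 0.05. With an estimated correlation the lowest adjusted p was 0.882, and with fry, which tests whether a list's genes move one way on balance, it was 0.246. By fry's test of change in either direction, which does not compare a list with other genes, 20 lists passed 0.05. In 7 lists the mean, the median and the direction of the camera test differed in sign: proteoglycan cores, epithelial junctions, mesenchymal transition, Notch, p53, NF-kB and TGF-beta. SDC1 was the only list member past 0.05 over all genes. Adjusted over the list alone, 19 members of 13 lists passed, 9 higher and 10 lower, with no correction for the number of lists. SDC1 was in the proteoglycan list because it was the siRNA target, so its count there is not independent evidence.

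**Figure D2:**
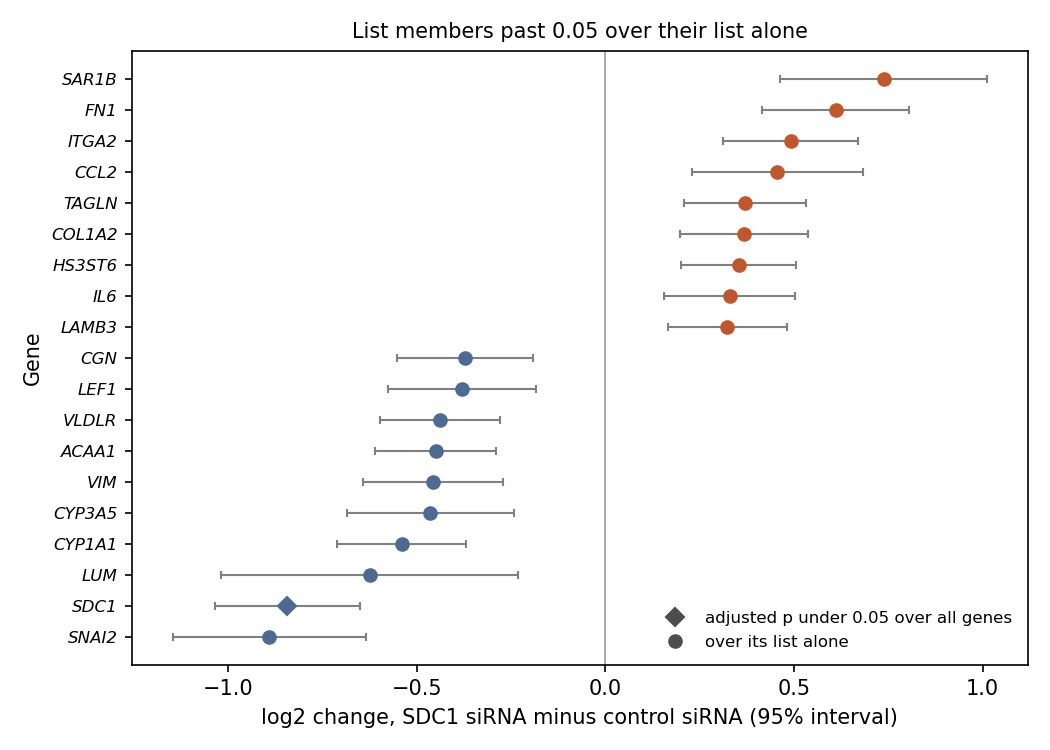
Log2 difference between SDC1 siRNA and control siRNA (n = 3 each) for the 19 list members whose adjusted p over their list alone was under 0.05, with 95% intervals from the limma fit. SDC1 (diamond) was the one member that also passed over all genes; 9 members were higher and 10 lower, from SNAI2 at -0.89 to SAR1B at 0.74.

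Other genes of the proteoglycan system showed no change that passed over all genes. Among 22 proteoglycan core proteins, SDC1 fell and the other 21 did not pass, including SDC4, syndecan-4, at 0.16 ± 0.07 (camera adjusted p = 0.836 for the list). Among 33 enzymes of heparan sulfate synthesis and remodelling (adjusted p = 0.661), HS3ST6, a 3-O-sulfotransferase, was 0.35 ± 0.07 higher and passed when adjusted over the list alone (adjusted p = 0.0212), although its 1 probe set was in the dimmest class. SULF2, which removes 6-O-sulfates, was at 0.31 ± 0.10 and did not pass. Of 22 binding and shedding partners of syndecans (adjusted p = 0.226), 0 passed, and the laminin receptor subunit ITGA6 was at 0.31 ± 0.09 (0.15 with the highest mean of centred values) and MMP9 at 0.23 ± 0.07. Among 34 genes of membrane trafficking and exosomes (adjusted p = 0.457), 0 passed, with TSPAN8 at 0.23 ± 0.08 and CD81 at 0.19 ± 0.07. The 1 probe set of TSPAN8 was in the dimmest class.

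Among 29 genes of epithelial-mesenchymal transition, 0 passed over all genes and 5 passed when adjusted over the list alone, in both directions. SNAI2 (adjusted p = 0.000968 over the list) and VIM, the intermediate filament vimentin (-0.46 ± 0.08, adjusted p = 0.00401 over the list), were lower. FN1 (adjusted p = 0.00107 over the list), the actin-binding protein TAGLN (0.37 ± 0.07) and the collagen chain COL1A2 (0.37 ± 0.07) were higher. VIM was named after its values were seen. The list as a whole had an adjusted p = 0.931, and its mean (-0.01) and median (0.04) differed in sign. FN1 rested on probe sets of shared sequence types: without them its difference was -0.04 (adjusted p = 0.949), measured by dim probe sets alone. It was 0.37 with the mean of all probe sets. Without those types TAGLN was at 0.08 ± 0.14 and COL1A2 at 0.12 ± 0.16, each from 1 probe set of a lower brightness class, and VIM had no probe set left. VIM was at -0.28 with the mean of its probe sets, of which the dim one was at -0.10 ± 0.10. COL1A2 and TAGLN also stood in the fibroblast and muscle list of 16 genes (adjusted p = 0.421), where they were higher and 7 genes were shared with the mesenchymal list. In it LUM, the matrix proteoglycan lumican, was lower (-0.62 ± 0.17, adjusted p = 0.0326 over the list; chosen after its values were seen), and at -0.42 without control replicate 2. LUM turned to 0.04 without probe sets of shared sequence types and was at -0.29 with the mean of all probe sets.

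In the adhesion and matrix lists, which do not hold MPDZ or ADAMTS18, 0 genes passed over all genes. Of 31 genes of epithelial junctions and polarity (adjusted p = 0.74), CGN, the tight junction protein cingulin, was at -0.37 ± 0.08 and passed over the list alone (adjusted p = 0.0408). CLDN15, a claudin, was at -0.25 ± 0.09. Of 36 integrin and focal adhesion genes (adjusted p = 0.429), the collagen receptor subunit ITGA2 was at 0.49 ± 0.08 and passed over the list alone (adjusted p = 0.00678), and was at 0.30 with the highest mean of centred values. Of 28 matrix and basement membrane genes (adjusted p = 0.348), FN1 and the laminin chain LAMB3 (0.32 ± 0.07) passed over the list alone. FN1 was at -0.04 without probe sets of shared sequence types, measured by dim probe sets alone. Of 32 members of the list of metalloproteinases, plasminogen activators and inhibitors, fixed without ADAMTS18, 0 passed by either adjustment. PLAT, the tissue plasminogen activator, was at 0.64 ± 0.15, from 1 probe set in the dimmest class. That list had the lowest camera value (adjusted p = 0.189), with 23 members above 0 and 9 below, and passed among genes of the brighter classes (adjusted p = 0.0484). That call was lost there with an estimated correlation (adjusted p = 0.608 with an estimated correlation).

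Signalling lists held 0 genes past the threshold over all genes. Of 25 Wnt target genes (adjusted p = 0.836), the transcription factor LEF1 was at -0.38 ± 0.09 and passed over the list alone (adjusted p = 0.0497), and the cyclin CCND1 was at -0.21 ± 0.09 and did not. In the stem cell list of 25 genes (adjusted p = 0.491) PROM1 was at 0.38 ± 0.11 and LIN28B at 0.18 ± 0.06, and in the Notch list of 28 genes (adjusted p = 0.836) MAML2 was at -0.36 ± 0.09 and HEY1 at -0.28 ± 0.08. In the growth factor and MAPK list of 41 genes (adjusted p = 0.421) FGFR2 was at -0.33 ± 0.08 and SPRED2, an inhibitor of ERK activation, at 0.29 ± 0.07. In the TGF-beta and BMP list of 33 genes (adjusted p = 0.566) the receptor TGFBR2 was at -0.47 ± 0.10 and the inhibitor SMAD7 at -0.28 ± 0.10. In the YAP target list of 25 genes (adjusted p = 0.348) DLC1 was at -0.32 ± 0.09 and RBMS3 at -0.28 ± 0.08. None of the members of these last 5 lists passed by either adjustment. Several depended on the choice of probe sets: with the highest mean of centred values TGFBR2 turned to 0.14 and DLC1 to 0.10 and LEF1 was at -0.20. Of the 3 LEF1 probe sets, 1 was at -0.59 ± 0.08 (limma adjusted p = 0.201 tested singly). The mean of all probe sets gave 0.13 for SPRED2, -0.12 for RBMS3, -0.17 for TGFBR2, -0.09 for DLC1 and -0.13 for FGFR2, and FGFR2 was at -0.04 without probe sets of shared sequence types.

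Genes of intestinal function did not move together past the threshold. Of 39 enterocyte differentiation genes, 27 were above 0 and 12 below with a median of 0.08 (adjusted p = 0.202), and 0 passed. The transcription factor GATA4 was at 0.31 ± 0.09, -0.10 with the highest mean of centred values and 0.08 with the mean of all probe sets. The adhesion molecule CEACAM1 was at 0.25 ± 0.07. Of the 5 CEACAM1 probe sets, 1 was at 0.62 ± 0.09 (limma adjusted p = 0.22 tested singly). Without control replicate 3 the list passed (adjusted p = 0.0266), as it did among genes of the brighter classes (adjusted p = 0.0484). Both calls were lost with an estimated correlation (adjusted p = 0.805 and adjusted p = 0.608 with an estimated correlation). In the lipoprotein and lipid absorption list of 31 genes (adjusted p = 0.386), SAR1B, a GTPase needed for chylomicron export, was at 0.74 ± 0.12 and the receptor VLDLR at -0.44 ± 0.07, and both passed over the list alone (adjusted p = 0.00338 each). SAR1B was at 0.32 without probe sets of shared sequence types, 0.41 with the mean of all probe sets and 0.17 with the highest mean of centred values. In the drug metabolism list of 37 genes (adjusted p = 0.421), the cytochromes CYP1A1 (-0.54 ± 0.08) and CYP3A5 (-0.46 ± 0.10) passed over the list alone. In the fatty acid list of 27 genes (adjusted p = 0.661), ACAA1, a peroxisomal thiolase, was at -0.45 ± 0.07 and passed over the list alone (adjusted p = 0.00434), and CPT2 was at -0.21 ± 0.09, or -0.14 without SDC1 siRNA replicate 2. In the cholesterol synthesis list of 19 genes (adjusted p = 0.421), 0 passed, with ACAT2 at -0.16 ± 0.07 and MSMO1 at 0.15 ± 0.08.

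Stress, proliferation and immune lists held 0 genes past the threshold over all genes. Of 40 interferon-stimulated genes, which double-stranded RNA can induce, 0 passed (adjusted p = 0.457). The leading members went opposite ways, ISG15 at 0.31 ± 0.07 and IFIT1 at -0.50 ± 0.13, but the 1 probe set of IFIT1 was in the dimmest class. Of 34 NF-kB and inflammatory genes (adjusted p = 0.774), the chemokine CCL2 (0.46 ± 0.10) and the cytokine IL6 (0.33 ± 0.08) passed over the list alone (adjusted p = 0.0377 each). Of 33 hypoxia and glycolysis genes (adjusted p = 0.199), 0 passed, with BNIP3L at -0.36 ± 0.10 and the glucose transporter SLC2A1 at -0.23 ± 0.07. Of 45 cell cycle genes (adjusted p = 0.348), 0 passed, with CENPF at -0.23 ± 0.07 and E2F8 at -0.29 ± 0.13. In the ATF4 and unfolded protein list of 33 genes (adjusted p = 0.491) VLDLR passed over the list alone, and ATF3 was at 0.24 ± 0.08. Of 24 p53 targets (adjusted p = 0.836) PLK2 was at -0.28 ± 0.10 and AEN at 0.15 ± 0.07. Of 33 apoptosis genes (adjusted p = 0.854) BIK was at 0.26 ± 0.07 and BCL2A1 at 0.25 ± 0.09, and of 13 RNA interference genes (adjusted p = 0.836) TNRC6B was at -0.21 ± 0.09 and AGO4 at 0.20 ± 0.09, with 0 passing in these 3 lists. Without control replicate 2, E2F8 was at -0.14, PLK2 at -0.19 and AGO4 at 0.13. CENPF was at -0.16 without probe sets of shared sequence types and at -0.13 with the highest mean of centred values, and AGO4 was at 0.35 with that rule and 0.12 with the mean of all probe sets.

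Lists of other cell types and of abundant transcripts were read in the same way. Of 29 goblet, Paneth and enteroendocrine markers (adjusted p = 0.202), 24 were above 0, with the hormone PYY at 0.33 ± 0.10 and the Paneth cell defensin DEFA6 at -0.32 ± 0.08. Of 16 leukocyte and endothelial markers (adjusted p = 0.39), CDH5 was at 0.37 ± 0.12 and VWF at 0.24 ± 0.09. Among 28 ribosomal proteins (adjusted p = 0.761), RPLP2 was at 0.13 ± 0.08, or -0.02 without probe sets of shared sequence types, and RPL3 at 0.07 ± 0.08. Among 31 respiratory chain subunits (adjusted p = 0.836), COX5A was at 0.12 ± 0.08 and NDUFA9 at -0.11 ± 0.08. In these 4 lists 0 members passed by either adjustment, and several values moved by over 1.5-fold when 1 array was left out. CDH5 was at 0.24 without control replicate 1, VWF at 0.16 without control replicate 2 and COX5A at 0.07 without control replicate 3, and RPL3 lay between 0.02 and 0.13. NDUFA9 was at -0.06 without SDC1 siRNA replicate 1 and RPLP2 at 0.07 without SDC1 siRNA replicate 2. With the mean of all probe sets PYY was at 0.07, VWF at 0.12 and RPLP2 at 0.06. The array's control probe sets for the 3' and 5' ends of GAPDH and ACTB, a sign of RNA integrity, gave 3' minus 5' signals that differed between SDC1 and control siRNA by -0.0028 and -0.11 on the log2 scale, with exact two-sided permutation p = 0.9 and p = 0.2.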

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

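The 5 called genes kept their sign under the alternatives run, but neither their calls nor always their size: with the highest mean of centred values GPRC5A shrank to 0.05 and ADAMTS18 to -0.09. The count of 5 genes became 39 with array weights (16 higher, 23 lower, all 5 among them), 11 with genes of step class 4 or higher (all 5 among them), 4 after quantile normalization again (SDC1 lost), 3 with the mean of all probe sets, 1 with the highest mean of centred values, and 0 with all probe sets singly, at an adjusted p of 0.01 or with the replicate block. The same 5 genes were called with the robust fit, with arrays centred on their medians and without _x_at and _s_at probe sets. The count ranged from 0 to 1 when 1 array was left out, which leaves fewer samples. SDC1 stayed at -0.84 with the replicate block (adjusted p = 0.0929), at -0.90 after quantile normalization (adjusted p = 0.083), at -0.83 with the highest mean of centred values (adjusted p = 0.0994) and at -0.83 for its weaker probe set tested singly (adjusted p = 0.121), none past the threshold. The same probe set passed as the gene's only one without _x_at and _s_at probe sets (-0.83, limma adjusted p = 0.0332). Over the 6 settings without 1 array SDC1 ranged from -0.92 to -0.78. Deviations from the group means gave no sign of pairing by replicate number. They correlated at -0.008, -0.263 and -0.113 for same-numbered arrays, and none correlated best with its own number. With 3 arrays per group this cannot exclude pairing, which the labels neither state nor deny. The cause of the lost calls was not tested. The number of lists past the threshold was 0 in the main test, 2 with step class 4 or higher (enterocyte differentiation and metalloproteinases, adjusted p = 0.0484 each) and between 0 and 1 with 1 array left out. With an estimated correlation, added after seeing the data for these settings, it was 0 in each. Named genes that had not passed reversed in 5 cases: FN1 became -0.0387 and RPLP2 -0.017 without _x_at and _s_at probe sets, and with the highest mean of centred values GATA4 became -0.10, TGFBR2 0.14 and DLC1 0.10. LUM, named after its values were seen, became 0.04 without _x_at and _s_at probe sets, where FN1 was measured by dim probe sets alone. Of the other pairs of a setting and a named gene other than SDC1, 1021 kept direction and side of the threshold, 19 came past it and 32, in 4 called genes, fell short of it. Over 1.5-fold moves were seen in 10 named genes without 1 array, in 14 with the highest mean of centred values, in 13 with the mean of all probe sets and in 7 without _x_at and _s_at probe sets. The rule for combining probe sets behind the main count, the step class filter and the singly tested SDC1 probe set with the smaller change were chosen after seeing the data. The highest mean was the main rule of the plan, and became an alternative only after the centring was seen. The planned filter on mean level and the intensity trend were not run, because centred values hold no level, nor was the robust option for the lists, which camera does not take. Signal over background could not be read, so no limit from it is given.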

Other observations

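The tests in this part were chosen after the result was seen, except for the splits of the test of change in either direction. Further genes were picked after their values were seen, did not pass over all genes and separated the groups completely. All 6 passed with array weights, and PLAAT4 also among genes of step class 4 or higher. In each other setting of the gene fit 0 of the 6 passed. The receptor tyrosine kinase ERBB4 was at -0.63 ± 0.09, the retinoid-responsive acyltransferase PLAAT4 at -0.63 ± 0.08, the immune checkpoint ligand VTCN1 at -0.53 ± 0.08, the adaptor BLNK at -0.63 ± 0.10, and TBC1D7, a subunit of the TSC complex, at -0.60 ± 0.08 (log2, limma standard error). The natriuretic peptide gene NPPB was at 0.49 ± 0.08. With the mean of all probe sets ERBB4 was at -0.10 and TBC1D7 at -0.34, and with the highest mean of centred values they were at -0.21 and -0.08. Among 19 genes past an adjusted p of 0.1, 14 were lower and 5 higher. A probe set with no gene symbol in the annotation had a difference of -1.19 ± 0.12 (adjusted p = 0.113 with probe sets tested singly), larger in size than that of any of the 5 called genes.

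With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 5 genes and the highest of the others gave 0. At an unadjusted p under 0.05 the counts were 2100 and 1545. List members past the threshold over their list alone numbered 19 in the real split and at most 2 in another. Lists past the camera threshold numbered 0 in the real split and at most 2 in another. By the test of change in either direction the real split gave 20 lists and the highest other gave 1. The split with 1545 genes set control replicates 1 and 2 with SDC1 siRNA replicate 3 against the rest. On the first principal component, with 35.3% of the variance, control replicate 2 stood at -22.1 and the other arrays between -2.1 and 11.6.

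Of the mesenchymal genes that passed when adjusted over the list alone, some lay on each side, with SNAI2 and VIM lower and FN1, TAGLN and COL1A2 higher. The samples were a cell line, with no stromal cells named in the titles, so a different share of such cells has no source in the design. A different share would move stromal markers to one side. Of 9 fibroblast and muscle markers outside the mesenchymal list, 2 were lower and 1 higher with intervals excluding 0. That is too few to decide from the markers alone. Each of the 5 genes kept at least 85% of its change when 1 array was left out, but genes picked for a low p over the same arrays would do so, and 1 array standing apart stays open. Probe sets that share sequence with other transcripts stay open for 4 of the 5 genes (all but SNAI2). These have only _x_at or _s_at probe sets in their brightest class, each with 1 gene symbol in the annotation. The suffix alone does not tell whether the shared transcripts are of another gene. A response to lower SDC1 is open as well.

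More of the leading genes were lower than higher, but among all genes at an unadjusted p under 0.05, 1074 were higher and 1026 lower. Silencing of other transcripts by the siRNA would add falls and may contribute. Of the 100 genes with the lowest p, 58 were lower with SDC1 siRNA. The larger side of the other splits held between 52 and 82 of 100, so this count decides nothing. The siRNA sequence is not given in the sources used here, and with 1 siRNA label per group, silencing of other transcripts and loss of SDC1 cannot be told apart.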
